A study of Mus musculus with 6 samples.

How the data were processed

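Total RNA of J1 mouse embryonic stem cells was taken by Trizol extraction, per the labels' protocols, turned into biotinylated cRNA, hybridised to one-colour Illumina Mouse-6 bead arrays and stained with streptavidin-Cy3. There were 6 arrays, 1 for each of Noggin and mock at days 0, 2 and 4, and the group of each array was taken from its label. The deposited table of each array holds 1 intensity per probe for 27496 probes, per the file headers. The values show that this intensity was neither background-subtracted nor scaled between arrays, with lowest values of 91.4 to 101.4 and medians from 152 to 176.55, and the 100 brightest probes held 17.06% to 19.69% of the summed signal. The scanner software and the choice of probes are not given in the sources used here, and no detection values came with the arrays. The authors' series matrix of 27495 probes is on a log2 scale, found by comparison with the array tables, and equals the log2 of the quantile-normalised intensity without background correction and without centring, with a median of 7.37 in every column. It was used as an alternative. For arrays, the number of arrays limits the precision.

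The array tables name probes by an identifier that the annotation table of the series matrix does not use. Each probe was therefore linked to the matrix row whose 6 values equalled its own quantile-normalised log2 values within 0.006, which gave 27491 links. All 2220 linked probes that carry a clone accession on both sides carried the same accession. Of the array probes, 19419 had 1 gene symbol, 6 had several and 8071 had none, for 13165 genes, and no gene was named from a probe with several symbols. For 19389 probes the Entrez identifier was found in a mouse gene table of the assembly GRCm38.p6, and 0 symbols needed an update. No coordinates are given, since no genome build is named with the arrays.

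Intensities were background-corrected with normexp (offset 50), quantile-normalised between arrays and put on a log2 scale with limma 3.58.1 in R 4.3.3. The design planned neqc with detection values where these exist and this setting where they do not, so the latter was used. Probes above the array median on at least 2 of the 6 arrays were kept, in place of a detection filter, which left 15364. One limma model with day and treatment as additive terms was fitted to the 6 arrays, with 4 coefficients, 2 residual degrees of freedom and 4.05 prior degrees of freedom, and gave 4 contrasts: Noggin against mock averaged over days, and the 3 pairs of days averaged over treatments. Benjamini-Hochberg adjustment was applied over all probes of a contrast at a threshold of 0.05. In the Noggin contrast the residual holds the difference of the effect between days as well as noise. On each single day Noggin and mock were compared by the difference of normalised log2 values, with no test, and probes above the median on both arrays that differed by at least 2-fold were counted. A difference is always Noggin minus mock, or later minus earlier day.

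The 20 gene lists held 383 genes: pluripotency, epiblast, BMP, Nodal and Wnt targets, primitive streak, cardiac, blood and endothelial, endoderm, neuroectoderm, trophoblast, fibroblast, metalloproteinases with their inhibitors, germ cell, glycolysis and hypoxia, cholesterol synthesis, p53 targets, stress (heat shock and unfolded protein response with the immediate-early genes Fos, Jun and Egr1 and the oxidative stress gene Hmox1), cell cycle, and ribosomal proteins. Several of them stand for other cell types that embryoid bodies or stem cell cultures can hold. Each gene was represented by its brightest probe on average. Lists were tested with limma camera (preset correlation 0.01), and again with an estimated correlation and with fry, adjusted over the lists. Camera with an estimated correlation takes its p-values from the 2 residual degrees of freedom. It could therefore hardly pass any list, and a failure under it decides little about a list. On single days a list's median was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. A gene that 2 lists hold counts in both. The groups, the tests, the lists, the rule for naming genes and all alternatives except those named next were fixed before the data were examined. An offset of 16 and a filter at the 75th percentile of both arrays were added after seeing the data.

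Named genes followed a rule. For each contrast these were the 10 largest rises and the 10 largest falls among probes with 1 symbol that passed and changed the same way in every pair, or, where too few passed, the largest average differences with the same sign in every pair, given as values only. For each single day they were the 5 largest differences on each side above the median of both arrays. Mmp3, Id1, Id2, Id3 and Nkx2-5 were always named, as were members of each list at its extremes or past the threshold. Genes outside the rule are said to be chosen after their values were seen. Where probes of a gene disagreed, the brighter was used in lists; among the named genes, the 2 probes of Tmsb10 changed in opposite ways from day 0 to day 4, by -0.70 and 0.43.

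The limma step was tested on simulated data with 200 of 15364 probes changed. The simulated Noggin change was the same on every day, so the shares below do not apply to an effect that differs between days. For Noggin against mock it recovered 84.5% of the probes changed by 1 on the log2 scale, with 8 false among 177 calls, and 100% of those changed by 2, with 17 false among 217. For day 2 against day 0 it recovered 61% with 4 false among 126 calls, and 97% with 10 false among 204.

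The alternatives tried were no background correction with a floor of 16, scaling to a common median, the authors' processed values, no filter, a filter at the median of all 6 arrays, which kept 11010 probes, a variance trend, a model without the other factor, and leaving out each day or array in turn. The closing section gives their effect. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Probes without a symbol entered all tests and counts but are not named.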

Results

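Gene expression was measured on 6 one-colour bead arrays of total RNA from J1 cells, a line of mouse embryonic stem cells. Cultures received either Noggin, a secreted antagonist of bone morphogenetic proteins (BMPs), at 150 ng/ml or a mock treatment, and were sampled at day 0 and as embryoid bodies, the free-floating aggregates in which such cells differentiate, at day 2 and day 4. According to the labels, the arrays were made to find the genes through which Noggin brings about cardiac differentiation. Each of the 6 groups, Noggin and mock at days 0, 2 and 4, was 1 array, so a difference between Noggin and mock on a single day has no replicate check and carries no p-value. Noggin was given for 3 days before the embryoid bodies formed and was withdrawn on the second day afterwards. Whether the day 0 Noggin array holds cells from before or after those 3 days is not settled. Its label names the treatment, with leukaemia inhibitory factor, while the design text lists both kinds of cells for that group. Contrasts with day 0 also set cells not yet in embryoid bodies against embryoid bodies. Time and culture conditions cannot be told apart in them. Each array gave a signal for 27496 probes, of which 19419 had 1 gene symbol. Median signal was 169.4 for Noggin and 167.35 for mock at day 0, 176.55 and 165 at day 2, and 159.8 and 152 at day 4, over lowest signals of 91.4 to 101.4. The 15364 probes above the array median on at least 2 arrays were tested with limma, with Benjamini-Hochberg adjustment. The p-values of probes measure only the spread between these arrays, since the labels do not say that arrays came from separate cultures. Camera p-values of lists, at the preset correlation, set a list against other genes and take its genes to be nearly independent. They can therefore be too small where the genes of a list vary together.

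Mmp3, which encodes the secreted protease named in the series title, was higher on the Noggin array at day 0. Its probes differed by 0.95 on the log2 scale each, 1.93-fold and 1.94-fold after normalisation, from signals of 706.8 against 389.2 and 1219.8 against 636.4. At day 2 the differences were 0.225 and -0.072, and at day 4 they were -0.12 and -0.34. Its signals were then between 161.7 and 195.8 at day 2 and between 128.4 and 155.2 at day 4, near or below the array medians. These later differences, the average over days and the sizes of the falls are therefore compressed by the floor. They do not show that a difference was absent or reversed at days 2 and 4. Averaged over the days, Mmp3 differed between Noggin and mock by 0.35 (SE 0.201) and 0.18 (SE 0.243), which limma did not separate from 0 (adjusted p = 0.969 for each). Over both treatments, Mmp3 fell by 2.03 (SE 0.246, limma adjusted p = 0.0035) and, at the other probe, fell by 3.07 (SE 0.297, limma adjusted p = 0.00201) from day 0 to day 2. From day 0 to day 4 it fell by 2.17 (SE 0.246, limma adjusted p = 0.00208) and fell by 3.37 (SE 0.297, limma adjusted p = 0.00109). Its differences from day 2 to day 4, -0.13 and -0.29, did not pass (limma adjusted p = 0.725 and 0.507).

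The BMP target genes Id1, Id2 and Id3, which encode inhibitors of basic helix-loop-helix factors, gave the background for the action of Noggin. The brighter Id1 probe differed between Noggin and mock by 0.14 at day 0, -0.46 at day 2 and 0.65 at day 4, and its dimmer probe by -0.24, -0.27 and 0.17. Id3 differed by 0.025, -0.38 and 0.60 on the same days. The brighter Id2 probe differed by 0.20, -0.097 and -0.0018. None of these genes passed the test of Noggin against mock averaged over days. The list of 8 BMP target genes had medians of 0.035 at day 0 and -0.11 at day 2, at the percentiles 74.94 and 9.62 of random lists. Across the days, the brighter Id1 probe rose by 2.32 from day 0 to day 4 (SE 0.249, limma adjusted p = 0.00178), and Id2 rose by 0.82 from day 0 to day 2 (SE 0.122, limma adjusted p = 0.00644). Id3 rose by 1.15 from day 2 to day 4 (SE 0.227, limma adjusted p = 0.0177). The cardiac transcription factor gene Nkx2-5 lay below the filter on dim probes, with signals between 147.2 and 166.7 on the 6 arrays, and was not tested.

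**Figure D1:**
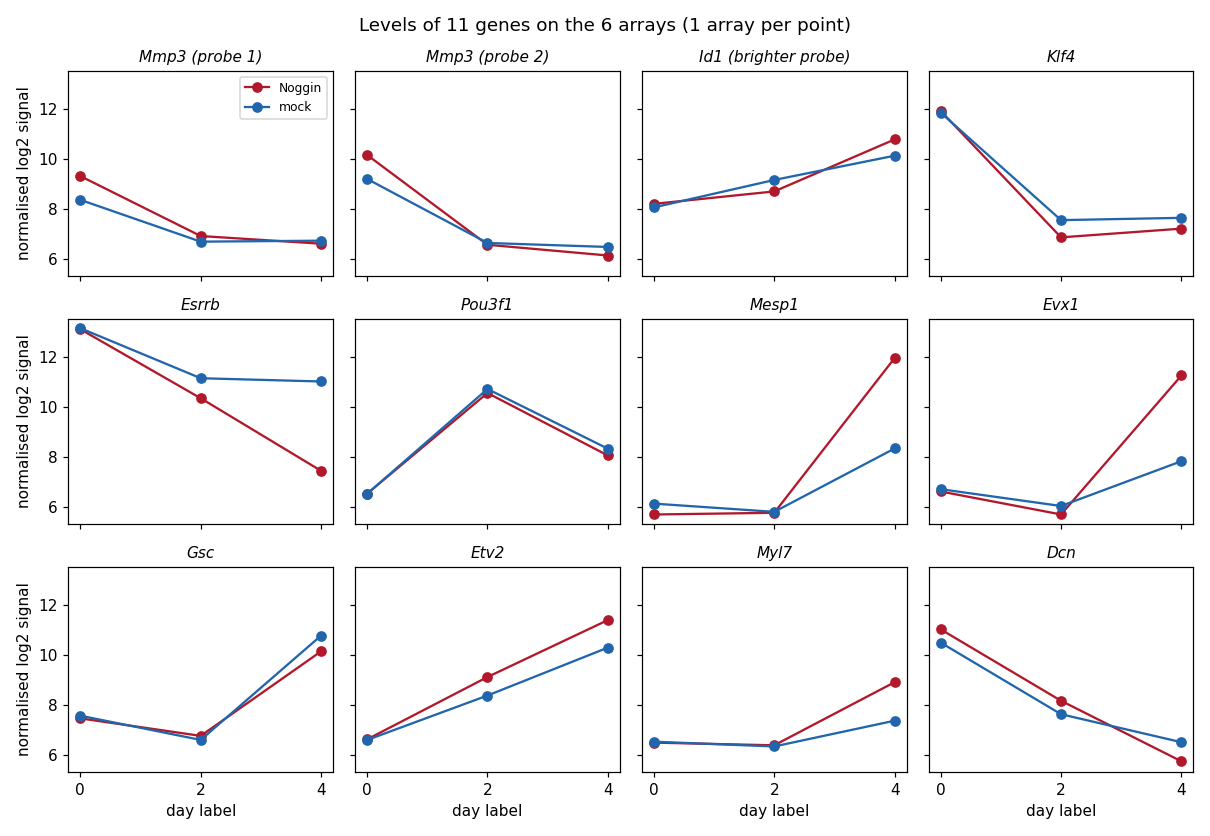
Normalised log2 signal (vertical axis) against the day of sampling (horizontal axis) for 12 probes, with Noggin arrays in red and mock arrays in blue and 1 array per point. Mmp3 was higher with Noggin at day 0 by 0.95 at both probes, Mesp1 was higher by 3.61 and Esrrb lower, at -3.57, at day 4.

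At day 0 the Noggin and mock arrays differed little, and Mmp3 showed the largest difference among named genes above the median on both arrays. After it came Il33, which encodes an alarmin cytokine, at 0.63, the TGF-beta receptor gene Tgfbr2 at 0.62, the acute-phase gene Saa3 at 0.58, and Dcn, which encodes the matrix proteoglycan decorin, at 0.53. The lowest were the proteasome subunit gene Psmb7 at -0.53, Tmsb10, which encodes an actin-binding thymosin, at -0.47, and Smndc1, Cdc42bpb and Scand1 at -0.46 each. Other metalloproteinase genes were also higher on the Noggin array, with Mmp2 at 0.44, Mmp13 at 0.39 and Mmp9 at 0.31. Of the 14 metalloproteinase and inhibitor genes above the filter on dim probes, to which all counts of list members refer, 10 were higher, and their median of 0.11 lay above 99.48% of 10000 random lists of the same size and expression. Fibroblast and interstitial matrix genes moved the same way, with 10 of 12 higher and a median of 0.12, above 99.67% of random lists. Endoderm genes were higher for 11 of 15 members, with a median of 0.093 at the percentile 98.82, and neuroectoderm genes were lower for 7 of 10, with a median of -0.11 at the percentile 1.11. Pluripotency genes were higher for 12 and lower for 12 of 24 members, with a median of 0.0011. The percentiles here and below describe 1 pair of arrays, ignore that genes of a list vary together, and were not adjusted over lists or days. Even a median beyond every random list can therefore reflect a difference between a pair of single cultures.

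No probe of 12980 above the median on both day 0 arrays differed by 2-fold or more, and 99.9% of these 12980 lay within 0.5. With an offset of 16 in place of 50 after background correction, 1 probe of Mmp3 reached a difference of 1.03 and the count became 1. The differences had an SD of 0.118, and across 1952 pairs of probes for the same gene, which are not independent replicates, they correlated with r = 0.145.

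At day 2, pluripotency genes were lower on the Noggin array, and genes of blood and endothelial precursors were higher. Of 24 pluripotency genes, 20 were lower, with a median of -0.25 that lay below every 1 of 10000 random lists. Among them Klf5 stood at -1.01, Tfcp2l1 at -0.88, and Esrrb and Klf2 at -0.80 each, all of which encode transcription factors of the naive pluripotent state, while Lin28a, which encodes an RNA-binding protein, was highest at 0.36. Blood and endothelial genes were higher for 6 of 8 members, with a median of 0.25 above 99.99% of random lists. They were led by Etv2, a factor required for both lineages, at 0.74, and by the blood factor gene Tal1 at 0.48, and Pecam1, which encodes an endothelial adhesion molecule that stem cells also carry, was lowest at -0.34. Median scaling moved the median of all probes at day 2 to 0.10 and gave medians of -0.17 and 0.28 for these lists.

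The other genes named at day 2 spanned unrelated functions. Higher on the Noggin array were the zinc-finger gene Zfp97 at 0.84, the ubiquitin ligase gene Ube4a and Prrc2c at 0.80 each, and Rraga, which encodes a GTPase of amino acid sensing, at 0.77. Lower were Ddx6, an RNA helicase gene, at -1.34, the acetyl-CoA acetyltransferase gene Acat3 at -1.02, Mtf2, which encodes a partner of Polycomb repressive complex 2, at -0.92, and the junctional adhesion molecule gene Jam2 at -0.88. Fibroblast genes were lower for 9 of 12 members, with a median of -0.15 at the percentile 1.4, and Fstl1 at -0.37 and Thy1 at -0.34 stood beside Dcn at 0.54 and Acta2 at 0.51. Glycolysis and hypoxia genes were lower for 13 of 16, with a median of -0.14 at the percentile 0.94. Under median scaling the fibroblast median was -0.071 and the glycolysis and hypoxia median -0.041. Only 9 of 12945 probes differed by 2-fold or more, 4 higher and 5 lower, and the named genes among them were Klf5, Acat3 and Ddx6. Without background correction 5 probes did, and under median scaling 13 did, 11 higher and 2 lower. The differences of pairs of probes for the same gene correlated with r = 0.403.

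At day 4 the Noggin and mock arrays differed far more widely. Mesp1 and Evx1, transcription factor genes of the primitive streak and nascent mesoderm, were 12.2-fold and 10.7-fold higher on the Noggin array, with Mesp1 signals of 3856.5 against 376.4. Vstm2b was higher by 2.84, the growth factor gene Igf2 by 2.63 and the myelin protein gene Pmp22 by 2.61. Lower were Dnmt3l, which encodes a cofactor of DNA methylation, at -3.64, the pluripotency factor gene Esrrb at -3.57, Zfp42, a classical marker of naive stem cells, at -3.23, the oocyte and embryo gene Ooep at -2.85, and Dppa4 at -2.63. In all, 295 of 12715 probes differed by 2-fold or more, 148 higher and 147 lower, for 116 and 110 named genes. Under median scaling 124 were higher and 177 lower.

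Of 24 pluripotency genes, 22 were lower on the day 4 Noggin array, 13 of them by 2-fold or more, and their median of -1.2 lay below every random list. Klf2 at -2.59, Tfcp2l1 at -2.49, Dppa2 at -2.26 and Gdf3 at -2.12 were among them, Pou5f1 stood at -0.96 and Nanog at -1.24, and Tbx3, which also acts in mesoderm and endoderm, was higher by 2.36. Germ cell genes were lower for 7 of 7 members, with a median of -0.14 at the percentile 9.655 and Rhox5 at -1.22. Genes of the post-implantation epiblast showed no common direction, with 6 of 12 higher, a median of 0.066 at the percentile 70.96, and Otx2 lowest at -0.53.

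Lists of mesoderm genes had medians above 0 on the same array. Primitive streak genes had a median of 0.76, above every random list, with 6 of 10 higher, 4 by 2-fold or more; besides Mesp1 and Evx1 these included Tbx6 at 2.14 and Eomes at 1.18, and Lhx1 stood at 0.78, whereas Cer1 at -0.81 and Gsc at -0.63 were lowest. Cardiac genes were higher for 8 of 9 members, with a median of 0.92 above every random list, but these 9 were the members above the filter among 20 with a probe, and the other 11 were not counted. The contractile protein genes Myl7, Myl4 and Myh7 stood at 1.54, 1.24 and 0.92, and the cardiac progenitor factor genes Isl1 and Gata4 at 1.02 and 0.96. Blood and endothelial genes were higher for 6 of 8, with a median of 0.67 above every random list, Gata2 at 2.05, Tal1 at 1.91 and Lmo2 at 1.39, and Pecam1 lowest at -1.13. These 8 and the 10 primitive streak genes were likewise only the members above the filter, among 16 with a probe in each list.

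Signalling targets parted at day 4. BMP target genes had a median of 0.63, above every random list, with 5 of 8 higher, Msx1 at 2.03, Hey1 at 1.50 and Smad6 at 1.26 ahead, and Id4 lowest at -0.51. Wnt target genes were higher for 6 of 6, with a median of 0.53 above 99.98% of random lists and Sp5 at 0.92. Nodal target genes were lower for 6 of 8, with a median of -0.71 below every random list, led by the Nodal inhibitors Lefty1 at -2.26 and Lefty2 at -1.15, followed by Cer1 and by Nodal at -0.79, while Eomes, which is also a streak gene, was higher.

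Other cell types and pathways differed on the day 4 arrays too. Genes of cholesterol synthesis were higher for 13 of 13 members, with a median of 0.84 above every random list and Hmgcs1 at 1.28, Nsdhl at 1.14 and Fdps at 1.11. Glycolysis and hypoxia genes were higher for 13 of 16, with a median of 0.27 at the percentile 99.98 and Egln3, which encodes an oxygen-sensing hydroxylase, at 1.37. Trophoblast genes had a median of 0.36 at the percentile 99.47, with 4 of 6 higher, the epithelial keratin gene Krt18 at 1.04 and Tfap2c at -1.18. Endoderm genes were split, with 7 higher and 8 lower, a median of -0.084 and a mean of 0.40, and Pdgfra at 2.09, Col4a2 at 1.76 and Col4a1 at 1.61 carried the mean. Fibroblast genes had a median of 0.11 at the percentile 80.44, with 7 of 12 higher and Fbln2 at 1.98. Genes of a mixed stress list, which holds heat shock, unfolded protein response, immediate-early and oxidative stress genes, were lower for 10 of 15, with a median of -0.20 at the percentile 0.62, and the amino acid stress genes Chac1, Asns and Atf4 stood at -1.91, -1.04 and -0.86. The p53 target genes had a median of -0.14 at the percentile 4.02 with Gadd45a at -0.88, neuroectoderm genes 0.13 at the percentile 88.11, metalloproteinase and inhibitor genes 0.067 at the percentile 68.27, and cell cycle genes -0.042 at the percentile 27.02. Ribosomal protein genes had a median of 0.014 at the percentile 57.62, and -0.060 under median scaling, which turned the sign of this list alone at day 4. Across 1858 pairs of probes for the same gene, the day 4 differences correlated with r = 0.647.

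**Figure D2:**
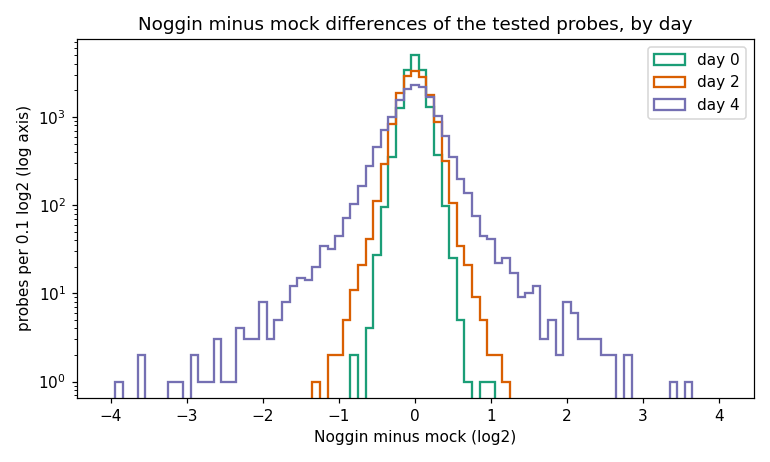
Number of tested probes (vertical axis, log scale) by their Noggin minus mock difference (horizontal axis, log2, in bins of 0.1) on each day, from 1 array per group. Over the probes above the median on both arrays of a day, the SD of the differences was 0.118 at day 0, 0.187 at day 2 and 0.378 at day 4.

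**Figure D3:**
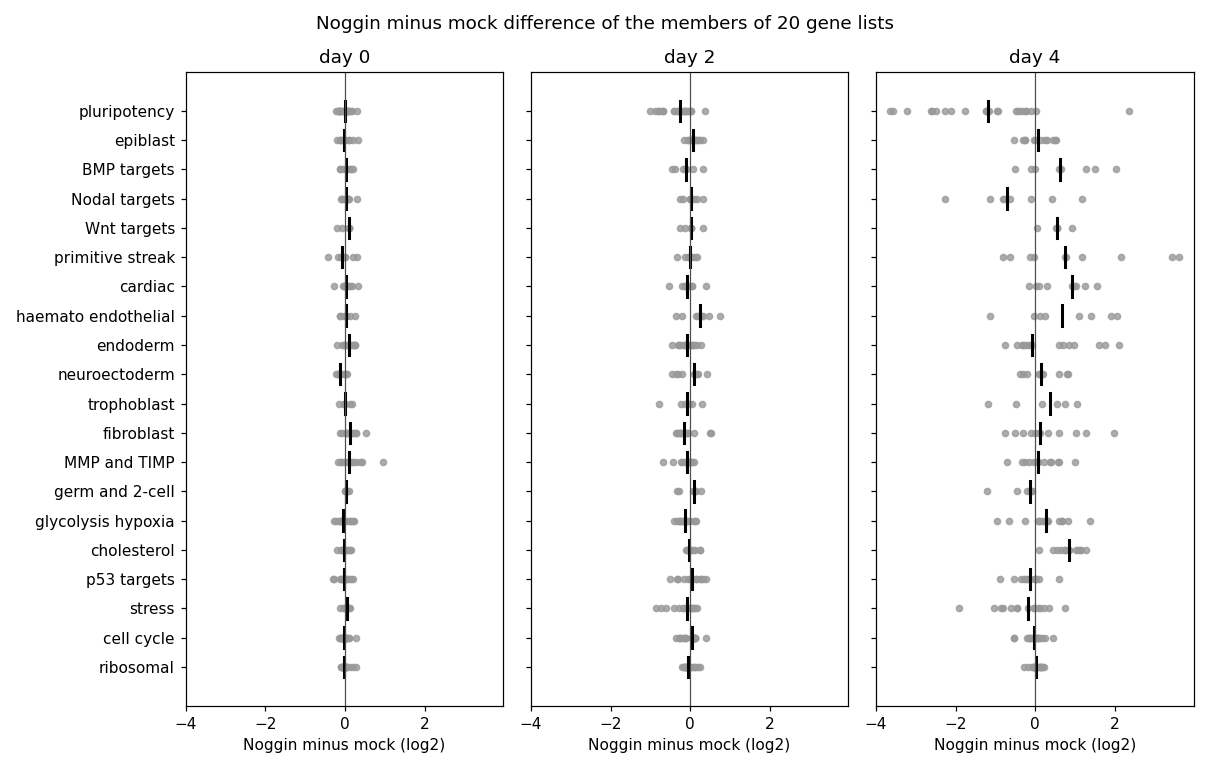
Noggin minus mock difference (horizontal axis, log2) of the members of 20 gene lists above the filter on dim probes at days 0, 2 and 4, with members as grey points and list medians as black bars, from 1 array per group. At day 4 the pluripotency median lies at -1.2 and the cardiac median at 0.92, and median scaling turns the sign of the cell cycle and p53 medians at day 0, of the primitive streak, cholesterol, stress and ribosomal medians at day 2, and of the ribosomal median at day 4.

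Averaging the Noggin effect over the 3 days asked which genes differed in the same way throughout. Among genes with the same sign on all 3 days, the largest averages belonged to those that differed mostly at day 4, namely Vstm2b at 1.17 (SE 0.489), the mesoderm factor gene Foxc2 at 1.12, Igfbp4 at 0.94, Klhl6 and the apelin receptor gene Aplnr at 0.89 each, Gata2 at 0.84, Apcdd1 at 0.83, Greb1 at 0.80, Nrp1 at 0.75 and Fbln2 at 0.74. On the other side stood Esrrb at -1.47 (SE 0.623), Dnmt3l at -1.37, Dppa4 at -0.96, Laptm5 at -0.94, Dppa2 at -0.85, AU018091 at -0.84, Arid5b at -0.82, Lgals3 at -0.81, Klf5 at -0.79 (SE 0.21) and a dimmer probe of Sox2 at -0.74. The brighter Sox2 probe averaged -0.385 and did not keep its sign, with 0.026 at day 0. None of these passed, and limma called 0 of 15364 probes, with a smallest adjusted p of 0.969 and 468 probes at an unadjusted p under 0.05. The count was also 0 under each alternative that kept all 6 arrays, with 419 probes at an unadjusted p under 0.05 without background correction, 322 under median scaling, 413 in the authors' processed values and 5 without day in the model. Without the day 4 arrays limma called 4 probes, of which the named gene was Acat3, at -0.69 (SE 0.121, adjusted p = 0.0379). Differences had the same sign on all 3 days for 3851 probes, 25.1%, where chance gives 25%.

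As a list, pluripotency genes were lower with Noggin averaged over the 3 days (median -0.42, limma camera adjusted p = 2.29e-09). Their medians were 0.0011 at day 0, where 12 were higher and 12 lower, -0.25 at day 2 and -1.2 at day 4. Cholesterol synthesis genes were higher (median 0.27, adjusted p = 0.000171), with medians of -0.023, -0.026 and 0.84 on the 3 days. Wnt target genes (median 0.14) and blood and endothelial genes (median 0.36) were higher at an adjusted p of 0.046 each, cardiac genes (median 0.22) were higher at 0.0483, and genes of the mixed stress list (median -0.023) were lower at 0.046. None of these 6 calls held with an estimated correlation (adjusted p = 0.712 with an estimated correlation for each), and fry gave 0.813 for each. No member of any list passed, either over all probes or adjusted over the list alone. Without the day 4 arrays the pluripotency call alone was left, at an adjusted p of 6.88e-05, while cholesterol and Wnt genes came to 0.911 each, cardiac genes to 0.917 with the opposite sign, blood and endothelial genes to 0.149 and stress genes to 0.498. Without the day 2 arrays blood and endothelial genes came to 0.0875 and stress genes to 0.123, and BMP target and metalloproteinase genes passed at 0.0395 each. Without the filter on dim probes the cardiac call was lost, at an adjusted p of 0.329, and germ cell genes passed, as lower, at 0.0221. With an offset of 16 the cardiac call (0.0904) and the stress call (0.0614) were lost. Without background correction, in the authors' processed values, which are the same data apart from rounding, and under median scaling, only the pluripotency and cholesterol calls passed. Median, mean and test differed in sign for neuroectoderm and cell cycle genes.

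From day 0 to day 2, on Noggin and mock arrays alike, many genes of the naive state fell and genes of the post-implantation epiblast rose. Pou3f1, which encodes a POU factor of the epiblast, rose by 4.11 (SE 0.119, limma adjusted p = 0.000251), and Wt1, which encodes a zinc-finger factor, rose by 4.43 (SE 0.192, limma adjusted p = 0.000522), with 2 arrays per day. Klf4, a core factor gene of the naive state, fell by 4.68 (SE 0.188, limma adjusted p = 0.00045). Socs3, a direct target gene of leukaemia inhibitory factor signalling, fell by 3.79 (SE 0.126, limma adjusted p = 0.000251). Also among the largest rises were the cyclin gene Ccno at 3.48, the growth factor gene Fgf15 at 3.27, Sall2 at 2.88, the Nodal inhibitor gene Lefty1 at 2.69, Gdf1 at 2.64, the chromatin organiser gene Satb1 at 2.63, Bcl11a at 2.62 and the carbonic anhydrase gene Car2 at 2.60. The further falls were those of the immediate-early gene Fos at -4.10, Emp1 at -3.86, Tbx3 at -3.52, Tfcp2l1 at -3.47, Nupr1 at -3.29, Igf2 at -3.23, the thrombomodulin gene Thbd at -3.12 and the annexin gene Anxa2 at -3.09.

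Of 12 epiblast genes, 8 rose, none fell and 4 did not pass, and 10 rose adjusted over the list alone. Besides those named, the risers included Pim2 at 2.42, Fgf5 at 2.22, Dnmt3b at 1.50 and Otx2 at 1.49. The list median was 1.5 (limma camera adjusted p = 2.52e-06, and adjusted p = 0.615 with an estimated correlation), and this was the list that also passed by fry (adjusted p = 0.00359). Of 24 pluripotency genes, 10 fell, 2 rose and 12 did not pass, and 13 fell adjusted over the list alone, with a list median of -0.65 (camera adjusted p = 0.00454, and adjusted p = 0.685 with an estimated correlation). Klf5 stood at -2.92, Tcl1 at -2.25, Nr5a2 at -2.07 and Nanog at -1.84, Lin28a rose by 0.64 and Eras by 0.51, and Pou5f1 at 0.17 did not pass (adjusted p = 0.608). Cholesterol synthesis genes rose for 11 of 13 members and for 12 adjusted over the list alone, with Fdps at 1.89 and Cyp51 at 1.82 and a median of 1.16 (camera adjusted p = 3.27e-05, and adjusted p = 0.685 with an estimated correlation).

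Fibroblast genes fell for 7 of 12 members and 5 did not pass; adjusted over the list alone, 8 fell and 1 rose. The falls were led by Fbln2 at -2.88, Dcn at -2.86 and Lox at -2.58, and the list median was -1.25 (camera adjusted p = 0.000678, and adjusted p = 0.685 with an estimated correlation). Glycolysis and hypoxia genes fell for 7 of 16, 1 rose and 8 did not pass, with Vegfa at -2.20, the glucose transporter gene Slc2a3 at -1.79 and Ldha rising by 0.96. Their median was -0.43, with 8 falls adjusted over the list alone (camera adjusted p = 0.00454, and adjusted p = 0.685 with an estimated correlation). Of 7 germ cell genes, 6 fell and Rhox5 rose by 1.36, and Kit, a receptor gene that is not restricted to germ cells, fell by 2.14, with a median of -0.68 (camera adjusted p = 0.00567, and adjusted p = 0.685 with an estimated correlation). Without the filter on dim probes the germ cell list no longer passed, at an adjusted p of 0.0537. Stress genes did not pass as a list (camera adjusted p = 0.0703).

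limma called 4207 of 15364 probes from day 0 to day 2, 2200 higher and 2007 lower, of which 1003 changed by 2-fold or more. With 1 array left out and 1 residual degree of freedom, the count was 363 without Noggin day 0, 770 without mock day 0, 798 without Noggin day 2, 1056 without mock day 2 and 7981 without either day 4 array. Among the named genes, Lefty1, Tbx3, Tfcp2l1, Nupr1 and Igf2 lost their calls without the Noggin day 0 array (adjusted p = 0.0658 to 0.214) and without the Noggin day 2 array (0.07 to 0.15). Lefty1, Tbx3, Nupr1 and Igf2 also lost them without the mock day 0 array (0.0738 to 0.152), and Lefty1, Tfcp2l1 and Nupr1 without the mock day 2 array (0.0634 to 0.177). All contrasts share the same residual, so a gap between Noggin and mock at day 4 also widens the errors here. Lefty1 changed by 2.683 and 2.699 in its pairs of arrays, with an SE of 0.559. Nupr1 changed by -3.315 and -3.273, with an SE of 0.755. The lost calls of such genes thus do not mean that their day 0 and day 2 arrays disagreed. Median, mean and test differed in sign for cardiac and for blood and endothelial genes.

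From day 0 to day 4, averaged over treatments, most genes of the primitive streak and epiblast lists rose and most pluripotency genes fell. Krt8, an epithelial keratin gene, rose by 4.60 (SE 0.163, limma adjusted p = 0.000368), and Etv2 rose by 4.23 (SE 0.247, limma adjusted p = 0.000513), with 2 arrays per day. Mesp1 rose by 4.23 with a wider error (SE 0.913, limma adjusted p = 0.015), by 6.25 on the Noggin and 2.20 on the mock arrays. Its day 0 values of 5.71 (Noggin) and 6.14 (mock) lay near the floor, below those of Nkx2-5, so the sizes of these rises are approximate. Lhx1, a factor gene of the anterior streak, rose by 4.19 (SE 0.205, limma adjusted p = 0.000368). Greb1 at 3.82, the Nodal co-receptor gene Cfc1 at 3.59, Krt18 at 3.55, the carbonic anhydrase gene Car4 at 3.51, the glutathione-degrading enzyme gene Chac1 at 3.50 and Grrp1 at 3.40 completed the largest rises. The largest falls were those of the lysosomal membrane gene Laptm5 at -5.01 (SE 0.405, limma adjusted p = 0.000904), Dcn at -4.63, Klf4 at -4.46, Emp1 at -4.12, Esrrb at -3.90, Jam2 at -3.85, Tfcp2l1 at -3.84, the nuclear receptor gene Nr5a2 at -3.69, Cobl at -3.50 and Igfbp7 at -3.48. The change of Esrrb was -5.66 on the Noggin and -2.13 on the mock arrays, and that of Tfcp2l1 -5.14 and -2.54.

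Primitive streak genes rose for 7 of 10 members, none fell and 3 did not pass, and 9 rose adjusted over the list alone. These 10 were the members above the filter among 16 with a probe. Members that stayed dim were left out, and a gene dim at day 0, such as Mesp1, entered only through later arrays. The filter thus favours rises among genes dim at day 0, in this and the other lists. Cer1 rose by 3.38, Eomes by 3.14, Gsc by 2.94, Fgf8 by 2.90 and Evx1 by 2.87, and the list median was 2.92 (limma camera adjusted p = 0.000158, and adjusted p = 0.515 with an estimated correlation). Of 24 pluripotency genes, 19 fell, 2 rose and 3 did not pass, and 20 fell adjusted over the list alone, with Zfp42 at -3.06, Tcl1 at -2.70 and Nanog at -1.93, while Lin28a and Eras rose. Their median was -2.01 (camera adjusted p = 2.1e-05, and adjusted p = 0.572 with an estimated correlation), and Pou5f1 at -0.44 did not pass (adjusted p = 0.151). Epiblast genes rose for 10 of 12, both over all probes and adjusted over the list alone, with Fgf5 at 3.24 and Sox4 at 2.22 and a median of 1.73 (camera adjusted p = 2.1e-05, and adjusted p = 0.515 with an estimated correlation). Endoderm genes rose for 7 of 15, 2 fell and 6 did not pass, and 8 rose adjusted over the list alone. Gata6 rose by 3.12, Col4a1 by 1.88 and Foxa2 by 1.66, Apoe fell by 1.08, and the median was 0.92 (camera adjusted p = 0.0194, and adjusted p = 0.572 with an estimated correlation).

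Cardiac genes did not pass as a list from day 0 to day 4 (median 1.07, camera adjusted p = 0.207), but 5 of 9 members rose, 2 fell and 2 did not pass, and 6 rose adjusted over the list alone. The cardiac actin gene Actc1 rose by 2.18, Myl7 by 1.63, Gata4 by 1.35, Myh7 by 1.09 and Isl1 by 1.07, and Smyd1 and Ryr2 fell. Cholesterol synthesis genes rose for 8 of 13, or 10 adjusted over the list alone (median 0.91, camera adjusted p = 0.00427, and adjusted p = 0.572 with an estimated correlation). Fibroblast genes fell for 6 of 12, with Lox at -3.15 and Col6a1 at -2.17 (median -0.64, camera adjusted p = 0.00318, and adjusted p = 0.572 with an estimated correlation). Germ cell genes fell for 6 of 7, with Rhox9 at -2.24 and Taf7l at -1.72 (median -1.49, camera adjusted p = 0.00335, and adjusted p = 0.572 with an estimated correlation). The p53 target genes fell for 9 of 14, 2 rose and 3 did not pass, with the cell cycle inhibitor gene Cdkn1a at -1.91, Plk2 at -1.80 and Mdm2 at -1.73 (median -0.91, camera adjusted p = 0.00604, and adjusted p = 0.572 with an estimated correlation). By fry 8 lists passed as well, but not the same ones. Epiblast, primitive streak, endoderm, fibroblast, germ cell and p53 target genes passed by both, pluripotency genes (adjusted p = 0.0627) and cholesterol genes (0.184) did not pass by fry, and trophoblast and cell cycle genes (0.0235 each) passed by fry alone.

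limma called 5952 probes from day 0 to day 4, 3019 higher and 2933 lower, of which 1549 changed by 2-fold or more. Without the Noggin day 0 array it called 879, and without the mock day 0 array 1865, and the Mesp1 and Esrrb calls were lost without the Noggin day 0 array (adjusted p = 0.14 and 0.102). Camera passed 8 lists, and 13 without the mock day 4 array.

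Between day 2 and day 4, most primitive streak genes rose, and 5 of 24 pluripotency genes fell. Krt8 rose by 5.12 (SE 0.163, limma adjusted p = 0.000486) and Lhx1 by 5.08 (SE 0.205, limma adjusted p = 0.000637), with 2 arrays per day. The secreted Nodal antagonist gene Cer1 rose by 4.74 (SE 0.257, limma adjusted p = 0.00084), and Sp5, a direct Wnt target, by 4.73 (SE 0.201, limma adjusted p = 0.000685). They were followed by the trypsin inhibitor gene Spink1 at 4.50, Cfc1 at 4.46, Mesp1 at 4.36, Igf2 at 3.78, Gsc at 3.77 and the endoderm factor gene Gata6 at 3.70. Wt1 fell by 3.71 (SE 0.192, limma adjusted p = 0.000809) and Lefty1 fell by 3.29 (SE 0.559, limma adjusted p = 0.0121). Fam25c at -2.96, Rpl39l at -2.95, the X-linked homeobox gene Rhox5 at -2.89, Dppa2 at -2.63, Gbx2 at -2.50, the carbonyl reductase gene Cbr3 at -2.48 and Pou3f1 and Ooep at -2.44 each completed the falls. The changes of Mesp1, Igf2, Lefty1, Dppa2 and Ooep were on the log2 scale more than 2 times as large on the Noggin as on the mock arrays. They were 6.18 against 2.53 for Mesp1, from day 2 values near the floor, and -3.74 against -1.14 for Ooep.

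Primitive streak genes rose for 7 of 10 members and 3 did not pass, with the same counts adjusted over the list alone (median 2.97, limma camera adjusted p = 0.000156, and adjusted p = 0.406 with an estimated correlation). The filter again left out members that stayed dim, which favours rises among genes dim at day 2 in this and the other lists. Endoderm genes rose for 8 of 15, or 10 adjusted over the list alone, with Col4a2 at 2.53 and Foxa2 at 1.69 (median 0.66, camera adjusted p = 0.00109, and adjusted p = 0.406 with an estimated correlation). In the trophoblast list the keratin genes Krt8, Krt18 and Krt7, which simple epithelia share, were the 3 of 6 members that rose (median 1.46, camera adjusted p = 0.0046, and adjusted p = 0.406 with an estimated correlation). Wnt target genes rose for 4 of 6, with Sfrp1 at 1.86 (median 0.86, camera adjusted p = 0.0215, and adjusted p = 0.674 with an estimated correlation). BMP target genes rose for 4 of 8, with Msx1 at 1.93 and Hey1 at 1.63 (median 1.02, camera adjusted p = 0.0334, and adjusted p = 0.669 with an estimated correlation). Glycolysis and hypoxia genes rose for 7 of 16, or 9 adjusted over the list alone, with Vegfa at 2.44 and Ndrg1 at 1.76 (median 0.65, camera adjusted p = 0.0027, and adjusted p = 0.669 with an estimated correlation).

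The p53 target genes fell for 9 of 14 and 1 rose, with Plk2 at -1.37 and Phlda3 at -1.17 (median -0.88, limma camera adjusted p = 0.00258, and adjusted p = 0.406 with an estimated correlation). Cell cycle genes fell for 5 of 19 and 14 did not pass, with Rrm2 at -0.69 and Mcm3 at -0.61 (median -0.27, camera adjusted p = 0.0215, and adjusted p = 0.406 with an estimated correlation). Pluripotency genes fell for 5 of 24 and 19 did not pass, with Gdf3 at -2.01 and Utf1 at -1.79, and 7 fell and 1 rose adjusted over the list alone (median -0.65, camera adjusted p = 0.0246, and adjusted p = 0.674 with an estimated correlation). That call was lost without the Noggin day 2 array (adjusted p = 0.0807) or the Noggin day 4 array (0.166), and the BMP target call without the Noggin day 2 array (0.0686). By fry 6 lists passed between day 2 and day 4. Pluripotency (adjusted p = 0.372), BMP target (0.114), Wnt target (0.073) and glycolysis and hypoxia genes (0.065) did not, and epiblast genes, which had not passed by camera, passed as lower (0.0319). Median, mean and test differed in sign for neuroectoderm and fibroblast genes.

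limma called 3954 probes between day 2 and day 4, 1968 higher and 1986 lower, of which 866 changed by 2-fold or more. With 1 array left out, the count was 148 without Noggin day 2, 368 without mock day 2, 1614 without either day 0 array and 7154 without mock day 4. The calls of Mesp1, Igf2, Lefty1, Fam25c, Rpl39l, Dppa2 and Ooep were lost without the Noggin day 2 array (adjusted p = 0.0846 to 0.277) and without the mock day 2 array (0.0503 to 0.123), and that of Rhox5 without the Noggin day 2 array (0.0661). Ooep (main adjusted p = 0.0438) also lost its call without either day 0 array (0.0555), without treatment in the model (0.0533) and with an offset of 16 (0.0605). Whether changes over days differed between Noggin and mock was not tested with a separate effect of Noggin for each day, a model that leaves no residual degree of freedom; a fit of the day 4 pair against the spread of the day 0 and day 2 pairs is given in the closing section.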

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

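No test was run in this part, and none was chosen after the result was seen. Fibroblast genes drew attention because their Noggin minus mock difference had opposite signs on different days: the median of 12 genes was 0.12 at day 0 and -0.152 at day 2. At day 0, 10 of the 12 were higher with Noggin, and at day 2, 9 of the 12 were lower. The signs were the same without background correction, in the authors' processed values, with an offset of 16 and under median scaling, where the day 2 median was -0.071. The difference between the days was not tested.

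Glycolysis and hypoxia genes drew attention for the same reason. Their median was -0.14 at day 2, with 13 of 16 genes lower, and 0.271 at day 4, with 13 of 16 higher. Under median scaling the medians were -0.041 and 0.20. The difference between the days was not tested.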

How the results depend on the processing

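The offset of 16 and the filter at the 75th percentile were chosen only after the data were seen. Counts of probes past the threshold stayed within 1.5 times the reported ones under every alternative that kept all 6 arrays: 0 for Noggin against mock, 3081 to 4696 for day 2 against day 0, 4351 to 6384 for day 4 against day 0 and 2986 to 4405 for day 4 against day 2. The days pair the arrays of the Noggin contrast by design and the treatments those of the day contrasts; with no replicate block, that is without the other factor, the counts were 0, 4696, 6384 and 4405. Median scaling raised the share of higher probes from 52.3% to 57.7% for day 2 against day 0, and moved the median of all Noggin minus mock differences at day 2 to 0.102, where 11 probes were 2-fold higher and 2 lower, against 4 and 5.

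The number of lists past the threshold for Noggin against mock fell from 6 to 2 with no background correction. It was also 2 under median scaling and in the authors' processed values, and 0 both with an estimated correlation and by fry. The cause of the falls to 2 and of that by fry was not tested. Without the filter on dim probes the number stayed at 6, but with germ cell genes (camera adjusted p = 0.0221) in place of cardiac genes (0.329). With an estimated correlation it was 0 for day 2 against day 0, 0 for day 4 against day 0 and 0 for day 4 against day 2. With 2 residual degrees of freedom this outcome was nearly fixed by the design, so it decides little about the lists. By fry, which does not set a list against other genes, the number was 1 for day 2 against day 0. It was 8 for day 4 against day 0, 6 of them the same lists, and 6 for day 4 against day 2, 5 of them the same. The count of probes differing 2-fold at day 2 was 5 with no background correction, where differences shrink by construction. At day 0 it was 1 with an offset of 16, which widens the differences of dim probes, and at day 4 it was 135 above the 75th percentile, where fewer probes are counted.

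Leaving out 1 day gave 0 to 4 probes and 1 to 6 lists for Noggin against mock. Leaving out 1 array, with 1 residual degree of freedom left and the lone array taken to vary like the others, gave 363 to 7981 probes (770 and 1056 without mock day 0 and day 2, 798 without Noggin day 2) and 6 to 7 lists for day 2 against day 0. It gave 879 to 8349 probes (1865 without mock day 0) and 8 to 13 lists for day 4 against day 0, and 148 to 7154 probes (1614 without either day 0 array) and 8 to 11 lists for day 4 against day 2. Among 148 probes without the Noggin day 2 array 81.8% were higher, and among 368 without the mock day 2 array 71.7%, against 49.8% with all arrays. Of 1201 values of named genes under the alternatives, 1131 kept their direction and side of the threshold, 38 kept the direction and lost the threshold, 36 of them with an array left out, and 0 changed direction. Genes named for a tested comparison had been chosen for the same sign in every pair of arrays, so that 0 says little about leaving out days or arrays. Another 32 untested differences moved by more than the spread, 12 smaller with no background correction, 12 smaller in the authors' values, which are the same data, 2 larger under median scaling and 6 larger with an offset of 16. Members of lists that the naming rule did not reach were not refitted with arrays left out. The planned normexp setting over all probes is the one reported, so it gave no separate values. The planned detection filters were not run for lack of detection values; filters at the array median took their place, and that at a detection p of 0.01 was not run. Signal over background limits dim genes: the lowest signals lay near 100 and the medians between 152 and 176.55, so differences of genes near the median, such as Nkx2-5, are compressed.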

Other observations

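The Mmp3 tests of probe noise and of a share of fibroblast-like cells were chosen only after the result was seen, as were the genes described in this paragraph and the next. Of these genes, Fos, Egr1 and Jun belong to the mixed stress list. That list did not pass from day 0 to day 2 or from day 2 to day 4 (limma camera adjusted p = 0.0703 and 0.341). Etv2 belongs to the blood and endothelial list and Klf5 to the pluripotency list. The other genes are single cases, with no list and no test of a group behind them. From day 0 to day 2, Stat3, a transcription factor gene, changed by -1.89 and -2.15 at its probes (limma adjusted p = 0.00146 and 0.000991), Junb by -1.38 (adjusted p = 0.00163), Ier3 by -2.27 (adjusted p = 0.00197), Egr1 by -2.48 (adjusted p = 0.0012) and Jun by -1.09 (adjusted p = 0.00707). Fos, Egr1 and Jun were higher again at day 4 than at day 2, by 1.62, 0.77 and 0.96 (limma adjusted p = 0.00221, 0.0271 and 0.0129). The day 4 Noggin array carried more Bmp4 than the mock array, by 1.73, after -0.61 at day 2, and Bmp4 itself had fallen by 2.03 from day 0 to day 2 (adjusted p = 0.0324).

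At day 4, Phlda2 was higher on the Noggin array by 2.22, Cdkn1c by 0.99 and the probes of Peg3 by 0.46 and 1.16 (1 array per group, not tested). Over both treatments Cdkn1c rose by 1.92 from day 0 to day 4 (limma adjusted p = 0.00375) and the Peg3 probes by 0.93 and 2.11 (adjusted p = 0.00971 and 0.00396), whereas Phlda2 at 1.53 did not pass (adjusted p = 0.0968). Of the 10 genes named at day 2, 7 did not keep their sign at day 4. Zfp97 and Rraga went from 0.84 and 0.77 to -0.88 and -0.77, and Mtf2 and Acat3 from -0.92 and -1.02 to 0.79 and 0.76. Ube4a and Prrc2c went from 0.80 each to -0.51 and -0.49, and Ddx6 from -1.34 to 0.30, while Etv2, Klf5 and Jam2 kept their signs. Across the 15364 tested probes, which are not independent replicates, day 2 and day 4 differences correlated with r = -0.0666 (Spearman -0.124), day 0 and day 2 with r = 0.144, and day 0 and day 4 with r = 0.0263.

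The wide gap between Noggin and mock at day 4, 295 probes at 2-fold or more against 9 at day 2, was weighed against 3 explanations. Background correction or scaling is argued against: the day 4 count was at least 23.2 times the day 2 count under each of 4 alternatives, of which no background correction and the authors' values are the same data apart from rounding, so that 3 are distinct. Random noise of single probes on the day 4 arrays is argued against as well, since differences of probes for the same gene correlated with r = 0.647. All probes of an array share its RNA and labelling, so this correlation cannot exclude variation of a whole day 4 array. A Noggin culture further along the shared course of differentiation stays open. Of the 295 probes, 61% differed in the direction of their day 2 minus day 0 change, between the bounds of 55% and 65% set beforehand. That held for 103 of the 147 lower probes and 77 of the 148 higher ones. The median day 2 minus day 0 change was -0.525 for the lower but 0.043 for the higher probes, whose sign therefore decides little. An effect of Noggin, and a difference between a pair of single cultures that has nothing to do with Noggin, cannot be told apart with 1 array per group.

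The higher Mmp3 on the day 0 Noggin array was weighed against 3 explanations as well. Probe noise is argued against, since the smaller of the differences of its probes lay 8.05 SD from 0. A larger share of fibroblast-like cells on that array would raise transcripts confined to such cells by about as much as Mmp3. The 7 fibroblast genes that fell from day 0 to day 2 had a median difference of 0.215 (SD 0.161). The highest of them, Dcn, stood at 0.528 against 0.95 for Mmp3. Whether the 7 genes are so confined was not tested, and Fstl1 still stood at 8.59 (Noggin) and 8.95 (mock) at day 2. The values thus argue against this explanation only as far as the genes are confined to such cells, and it may still account for part of the difference. An inflammatory activation stays open. A list of 13 genes of that response had a median of 0.0246 at the percentile 66.81 of random lists, below the 90th set beforehand to exclude it, but 9 of the 13 were higher, Ccl7 most at 0.379. The list also left out the alarmin gene Il33 at 0.63 and the acute-phase gene Saa3 at 0.58, both among the 5 highest named genes that day, so this bound was too weak to decide, a reading adopted after the result was seen. Also open are an effect of Noggin on Mmp3, untested with 1 array per group and with the state of the day 0 Noggin cells unsettled, and a difference between the cultures.

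For Noggin against mock averaged over days, the real split of the 6 arrays into 3 and 3 gave 0 probes, so all 10 splits reached its count by construction and their count decides nothing. With 10 splits the share can never fall under 0.05 in any case. The highest other gave 1801. The splits with 1801 probes set 1 day 4 array and both day 0 arrays against the rest, so with day in the model they part the arrays of day 4 alone. They are the Noggin minus mock difference of day 4, 1 array against 1, set against the pairs of day 0 and day 2, and the structure of the samples that they show is the day 4 gap weighed above.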
